A study of Homo sapiens with 12 samples.

How the data were processed

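RNA from 12 samples of MDA-MB-231 cells was profiled on one-colour Affymetrix arrays, 3 arrays in each of 4 groups: parental and treated-to-resistance (TTR) cells, each without and with TRAIL at 100 ng per ml for 2 hours. Per the labels' protocols, total RNA was extracted with Trizol and biotin-labelled cRNA was made from it. The deposited values are on a log2 scale and, per the submitters' processing notes, the authors made them with RMA in Affymetrix Power Tools. As usually run, RMA corrects background, brings the probes of all arrays to a common distribution and summarises them per feature. The versions and settings of that step and the genome build behind the features are not given in the sources used here, and no coordinates are printed. Signal above background was not called by any detection measure used here, so low levels can be background. The highest level of any feature was 13.9.

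Such a step removes changes in total RNA per cell, and without a spike-in each value is relative to the rest of its array. The deposited features do not share one distribution, since the array medians differed between groups, and the step behind that is not given in the sources used here. Counts of called genes, list tests, named genes and the RNA classes described last were therefore recomputed after centring each array on its median and after a further quantile normalization. Other values were not, such as correlations, the median response in each line and the other tests that weigh explanations.

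The table held 33252 features. With the platform annotation supplied for this work, 19460 features named 1 gene, 1754 named several and 12038 were not named. Of the features with 1 gene, 19429 had a gene identifier that matched the RefSeq gene table of assembly GRCh38.p14, which was used for names only and changed 0 symbols. Features naming several genes or none were not used for named genes. For the 769 genes with more than 1 feature, the feature with the highest mean over all arrays was kept, which gave 18417 genes. Among the named genes, which alone were checked for this, the features of PECAM1 and KRT18 differed in sign from one another in at least one comparison. With the mean of all features of a gene, 8 genes called for TRAIL in parental cells were called the other way. The same held for 3 genes for TTR against parental cells with TRAIL and 2 for the difference between the TRAIL effects. No filter on low values was applied in the reported results. No 2 arrays held identical values (0 pairs), and 0 columns were without a sample.

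Groups were taken from the sample labels. The comparisons were TRAIL against untreated in each line, TTR against parental cells without and with TRAIL, and the difference between the lines in the TRAIL effect. All 12 arrays were fitted together with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, one mean per group, no block), leaving 8 residual degrees of freedom and 7.87 prior degrees of freedom. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over genes, and genes with an adjusted p under 0.05 were called. An exact permutation test of 3 against 3 arrays cannot go below 0.1, so none was used for single genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

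Before the data were examined, 22 gene lists, the rule for named genes, the tests and most alternatives were fixed. The lists were NF-kB target genes, immediate-early and AP-1 genes, TRAIL receptors and death-inducing signalling complex, caspases and pro-apoptotic genes, anti-apoptotic genes, SLC26 anion transporters, sulfation and heparan or chondroitin sulfate synthesis, O-glycosylation of death receptors, interferon-stimulated genes, antigen presentation, unfolded protein and integrated stress response, p53 target genes, proliferation genes, mesenchymal genes, epithelial genes, cholesterol synthesis and uptake, hypoxia and glycolysis genes, NRF2 and oxidative stress genes and ribosomal protein genes. Markers of luminal breast cells, blood cells, and fibroblasts and endothelium stood for other cell types. Lists were tested with camera, which asks whether a list moves more than other genes, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the 22 lists of a comparison. camera with an estimated correlation and fry were alternatives. fry asks whether the genes of a list move one way on balance and does not compare them with other genes.

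Named genes followed a rule. In each pairwise comparison they were the 10 largest rises and the 10 largest falls among called genes whose 3 against 3 values did not overlap, and for the difference between the lines the 10 smallest p-values. From each list described, they were the 4 called members with the smallest p-value, or the 2 with the smallest p-value as values only where none was called. SLC26A2 and the 11 measured of the 14 members of the TRAIL receptor list were reported in every comparison. TNFRSF10C, RIPK1 and TRAF2 of that list were not among the genes tested, so nothing is said of them. Examples were drawn from these genes. Features with several genes or none, XIST and Y-linked genes were not named, and values of multigene families (small nucleolar RNA, histone, class II, metallothionein, MAGE, ribosomal protein and olfactory receptor genes) are uncertain. Genes named outside the rule are said to have been chosen after their values were seen.

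The fit and list test were checked on simulated data with 18417 genes. Each gene kept its mean over all arrays and its fitted variance, and varied independently of the others. Of the genes, 67, 67 and 66 were changed by 0.5, 1 and 2 on the log2 scale. At 0.5 the share recovered was 56.7% for TRAIL in parental cells, 61.2% for TRAIL in TTR cells, 64.2% for TTR against parental cells without TRAIL, 65.7% with TRAIL and 16.4% for the difference between the TRAIL effects. At 1 it was 100% in the 4 pairwise comparisons and 95.5% for the difference, and at 2 it was 100% in all 5. False calls made up 5.0%, 7.4%, 6.4%, 6.3% and 4.7% of the calls. A list shifted by 0.5 was called in each comparison and 0 others were, by camera. Since the simulated genes were not correlated and few were changed, this check does not cover list calls among correlated genes or broad changes.

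Alternatives were the replicate number as a block, leaving out the third of genes with the lowest mean (below 3.87), median centring, quantile normalization, only the 2 groups compared in the fit, the mean of all features of a gene, every feature of the table, a variance trend with robust estimation, array weights, changes of at least 2-fold and leaving out each array in turn. Leaving the 3 TRAIL-treated parental arrays out of the fit, and the replicate block with only the 2 TTR groups in the fit, were added after the data were seen. Where one array is left out its group keeps 2 arrays. The sample descriptions share a code per replicate number across groups, whose meaning is not given in the sources used here. Same-numbered arrays of TTR cells without and with TRAIL deviated together from their group means (correlations across genes of 0.322, 0.146 and 0.395). Each was over 0.1, so the numbers were taken to pair these 2 groups, which the labels do not state. The pairing was decided for this comparison after its counts of calls had been seen. In the other comparisons not every such correlation was over 0.1.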

Results

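Transcript levels were measured in MDA-MB-231 cells, an established human triple-negative breast cancer line, in a parental form and in a derivative that had been treated until it was resistant (TTR). TRAIL, the death ligand that binds TNFRSF10A and TNFRSF10B at the cell surface, was given at 100 ng per ml for 2 hours, and untreated cells of each form were the control. Each of the 4 groups held 3 arrays, 12 in all, and 18417 genes were tested. The number of arrays limits the precision, and since the labels do not say that the replicates were separate cultures, the p-values measure only the spread between these arrays. The sample descriptions also carry a tag, not explained in the sources used here, with one form in parental and another in TTR arrays. Whatever it marks cannot be told apart from the line in any comparison of TTR with parental cells. In what follows n = 3 arrays per group, changes are on the log2 scale, and the value after ± is the standard error (SE) from the limma fit, unless it is called an SD.

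The 3 arrays of TRAIL-treated parental cells stood apart from the other 9. Their median over all features on the array was 4.58 to 4.61, against 4.24 to 4.31 in the untreated arrays and 4.38 to 4.40 in TRAIL-treated TTR cells. They correlated with the other groups at 0.921 to 0.963 across features, which are not independent replicates. The other groups correlated with one another at 0.985 to 0.992 and arrays of one group at 0.989 to 0.995. The median of all features was 0.29 higher with TRAIL than without in parental cells and 0.11 higher in TTR cells. TTR minus parental was −0.02 without TRAIL and −0.20 with it. Changes relative to these shifts of the median are given below as values after median centring. The parental TRAIL arrays also held a narrower range of values. Their lower quartiles were 2.98 to 3.05, against 2.84 to 2.89 in untreated parental arrays. Their upper quartiles were 6.545 to 6.593, against 6.649 to 6.691. Median centring moves all features of an array alike and does not undo this.

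**Figure D1:**
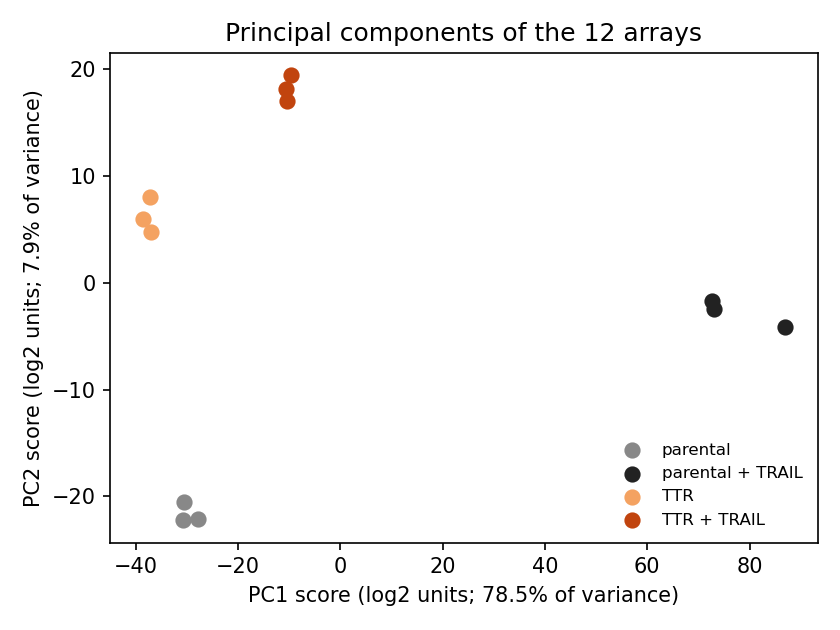
Each point is 1 of the 12 arrays, placed by its scores on the first principal component (78.5% of the variance, horizontal axis) and the second (7.88%, vertical axis) of the log2 values, and coloured by group. The 3 parental arrays with TRAIL lie between 72.7 and 87.0 on the first component, the 3 TTR arrays with TRAIL between −10.7 and −9.65, and the 6 untreated arrays between −38.6 and −27.8.

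The first comparison asked which transcripts changed in parental cells within 2 hours of TRAIL. Immediate-early genes rose as a group. FOS and FOSB, subunits of the AP-1 transcription factor, rose 72.1-fold (6.17 ± 0.14, adjusted p = 2.48e-14) and 70.8-fold (6.15 ± 0.13). EGR1 rose 38.8-fold (5.28 ± 0.12) and JUNB 17.8-fold (4.15 ± 0.10). Of the 36 measured immediate-early and AP-1 genes, 34 rose and 0 fell by limma, the same numbers adjusted over the list alone and at an unadjusted p under 0.05. The list's median was 2.34, or 2.05 after median centring, and camera called it higher than other genes (adjusted p = 9.61e-20, and adjusted p = 0.0134 with an estimated correlation). NF-kB target genes rose as a group. The neutrophil chemokines CXCL2, CXCL8 and CXCL1 rose 58.1-fold (5.86 ± 0.15), 43.4-fold (5.44 ± 0.17) and 36.6-fold (5.20 ± 0.17). NFKBIZ, an atypical inhibitor of NF-kB, rose 7.58-fold (2.92 ± 0.10). Of 31 measured NF-kB targets 26 rose, 2 fell and 3 did not pass, with the same numbers adjusted over the list alone. The list's median was 1.60, or 1.30 after median centring (camera adjusted p = 4.63e-10, and adjusted p = 0.255 with an estimated correlation). The 2 that fell, which were chosen after their values were seen, were NFKB1 (−1.55 ± 0.13), a subunit of NF-kB itself, and CYLD (−0.80 ± 0.10), a deubiquitinase that restrains it. Among the other large rises, the signalling regulator RGS2 rose 67.0-fold (6.07 ± 0.20). The transcription factor SNAI1, a repressor of epithelial genes, rose 49.9-fold (5.64 ± 0.16) and the helix-loop-helix inhibitor ID2 43.4-fold (5.44 ± 0.30).

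Among the 10 largest falls in parental cells, HACD3, an enzyme of fatty acid elongation, fell 8.69-fold (−3.12 ± 0.21), PIGB, which builds membrane anchors, 7.76-fold (−2.96 ± 0.11), and IDH3A of the citric acid cycle 7.20-fold (−2.85 ± 0.13). The deadenylase CNOT7 fell 6.83-fold (−2.77 ± 0.22) and the sterol oxidase MSMO1 6.26-fold (−2.65 ± 0.17). Of 19 measured genes of cholesterol synthesis and uptake, 4 rose and 13 fell (median −0.76, camera adjusted p = 0.0291, and adjusted p = 0.685 with an estimated correlation). SC5D fell 4.70-fold (−2.23 ± 0.12) and SCD 2.89-fold (−1.53 ± 0.12), while FASN, the fatty acid synthase, rose 2.98-fold (1.58 ± 0.13). Of 32 proliferation genes 6 rose and 22 fell (median −0.59, camera adjusted p = 0.0134, and adjusted p = 0.686 with an estimated correlation). The replicative helicase subunit MCM6 (−1.75 ± 0.12), the licensing factor CDC6 (−1.31 ± 0.13) and cyclin CCNA2 (−0.99 ± 0.10) fell, whereas the replication clamp PCNA rose (1.01 ± 0.10). Of 20 NRF2 and oxidative stress genes 2 rose and 11 fell (median −0.56, camera adjusted p = 0.0291, and adjusted p = 0.685 with an estimated correlation). PGD of the pentose phosphate pathway fell 3.26-fold (−1.71 ± 0.11) and GCLC of glutathione synthesis 2.93-fold (−1.55 ± 0.12), and the metallothionein MT1X rose 5.82-fold (2.54 ± 0.11). The counts in these 3 lists were the same adjusted over the list alone. After median centring their medians were −1.05, −0.89 and −0.85, and after quantile normalization −0.64, −0.41 and −0.70. The camera calls of the 3 lists were lost with either scaling (cholesterol 0.118 and 0.299, proliferation 0.0804 and 0.479, NRF2 0.117 and 0.173) and without the third of genes with the lowest mean (0.293 for each).

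SLC26A2, the sulfate transporter named in the series title, fell 2.30-fold with TRAIL in parental cells (−1.20 ± 0.16, adjusted p = 4.69e-06), from 6.32 (SD 0.30) to 5.12 (SD 0.29). Of the 11 measured members of the list of TRAIL receptors and death-inducing signalling complex, 1 rose and 6 fell, the same numbers adjusted over the list alone, and the list did not pass (median −0.35, or −0.64 after median centring, camera adjusted p = 0.231). The decoy receptor TNFRSF11B fell (−0.95 ± 0.13), as did the adaptor TRADD (−0.60 ± 0.15), the death receptors TNFRSF10B (−0.57 ± 0.13) and TNFRSF10A (−0.49 ± 0.11), CFLAR (−0.47 ± 0.09), an inhibitor of caspase activation, and the adaptor FADD (−0.35 ± 0.12, adjusted p = 0.0192). The decoy receptor TNFRSF10D rose (0.40 ± 0.11). CASP8 (−0.11), CASP10 (−0.35), FAS (0.05) and TNFSF10 (−0.27), which encodes TRAIL, did not pass (adjusted p = 0.381, 0.0845, 0.717 and 0.229). FADD no longer passed without parental untreated array 1 (0.0946) or parental TRAIL array 3 (0.117) or after quantile normalization (−0.08, adjusted p = 0.626), and its adjusted p over all alternatives was 2.37e-04 to 0.626. TNFRSF10B was lost with quantile normalization (−0.30, adjusted p = 0.0506, range 1.50e-05 to 0.0506), TNFRSF10D with median centring (0.11, adjusted p = 0.380, range 4.76e-05 to 0.380) and CFLAR with the mean of all features of the gene (−0.24, adjusted p = 0.0565, range 8.49e-07 to 0.0565). With median centring FADD stood at −0.64, TNFRSF10B at −0.86, TNFRSF10A at −0.78 and CFLAR at −0.76, and CASP8 (−0.40), CASP10 (−0.64) and TNFSF10 (−0.56) passed (adjusted p = 0.0025, 0.0028 and 0.0123, with ranges reaching 0.818, 0.203 and 0.536). CASP10 and TNFSF10 also passed after quantile normalization (0.0111 and 0.0348), and CASP10 with only these 2 groups in the fit (0.0147).

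In all, 10827 genes (58.8%) changed with TRAIL in parental cells, 5319 higher and 5508 lower, with 776 higher and 2439 lower by at least 2-fold. The split between higher and lower depended on the scaling and the features used: 49.1% of the called genes were higher as deposited, 21.3% (2328 higher, 8608 lower) after median centring and 37.9% (3524 higher, 5783 lower) after quantile normalization. Without the third of genes with the lowest mean it was 42.6% (3980 higher, 5365 lower). Over every feature of the table, those with no gene named here included, it was 58.2% (10004 higher, 7189 lower).

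The second comparison asked how the same TRAIL dose acted on TTR cells. Immediate-early genes again rose as a group. EGR1 rose 29.8-fold (4.90 ± 0.12, adjusted p = 2.14e-13), FOS 23.1-fold (4.53 ± 0.14) and FOSB 11.4-fold (3.51 ± 0.13). JUNB rose 6.63-fold (2.73 ± 0.10). Of the 36 immediate-early and AP-1 genes 29 rose, 0 fell and 7 did not pass by limma (32 rose adjusted over the list alone and at an unadjusted p under 0.05, with 0 falling). Their median was 0.84, or 0.74 after median centring (camera adjusted p = 2.89e-53, and adjusted p = 4.01e-04 with an estimated correlation). CXCL2 rose 21.3-fold (4.41 ± 0.15), CXCL8 19.5-fold (4.28 ± 0.17), TNFAIP3, a deubiquitinase that ends NF-kB signalling, 13.3-fold (3.73 ± 0.20) and the inhibitor NFKBIA 6.15-fold (2.62 ± 0.11). Of 31 NF-kB targets 24 rose, 0 fell and 7 did not pass by limma (26 rose adjusted over the list alone and at an unadjusted p under 0.05, with 0 falling). Their median was 1.06, or 0.95 after median centring (camera adjusted p = 1.84e-42, and adjusted p = 0.0041 with an estimated correlation). PTX3, a secreted pattern-recognition molecule, rose 7.18-fold (2.84 ± 0.18). The largest falls stayed under 2-fold. PLA2G4A, which releases arachidonic acid, fell 1.78-fold (−0.83 ± 0.10, adjusted p = 1.02e-04), PIGB 1.76-fold (−0.82 ± 0.11) and the serine racemase SRR 1.76-fold (−0.82 ± 0.12). SLC26A2 did not pass (−0.40 ± 0.16, adjusted p = 0.152), but it did after median centring (−0.50, adjusted p = 0.0417), with array weights (−0.39, adjusted p = 0.0479) and with the replicate number as a block in a fit of the 2 TTR groups alone (adjusted p = 0.0258, range over alternatives 0.0258 to 0.426). Of the 11 receptor and signalling complex genes only TNFRSF10D passed (0.46 ± 0.11, adjusted p = 0.0189), the same count adjusted over the list alone. This call was lost without TTR untreated array 2 (0.095) or 3 (0.0684) or TTR TRAIL array 1 (0.0786) or 2 (0.105), over a range of 9.45e-04 to 0.105. TNFRSF10A was at −0.03, TNFRSF10B at −0.15, CASP8 and FADD at −0.08 each, CFLAR at 0.01, FAS at −0.10, CASP10 at 0.16, TRADD at −0.20, TNFRSF11B at −0.27 and TNFSF10 at −0.44, with adjusted p from 0.190 to 0.952. TNFSF10 passed in the blocked fit of the 2 TTR groups (adjusted p = 0.0101, range over alternatives 0.0101 to 0.561).

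In TTR cells 1072 genes (5.82%) changed, 602 higher and 470 lower, with 3794 genes at an unadjusted p under 0.05. By limma, 124 rose and 0 fell by at least 2-fold. The count fell to 450 (330 higher, 120 lower) without TTR untreated array 2, 542 (413 and 129) without TTR untreated array 3, and 508 (373 and 135), 379 (293 and 86) and 693 (471 and 222) without TTR TRAIL arrays 1, 2 and 3. It was 2391 (448 higher, 1943 lower) after median centring, which took the higher share from 56.2% to 18.7%. It was 956 (449 and 507) after quantile normalization, 1312 (631 and 681) with only these 2 groups in the fit and 3199 (1421 and 1778) with array weights. In alternatives added after the data were seen, it was 1709 (733 and 976, 1059 of them shared) with the parental TRAIL arrays out of the fit. It was 2670 (1122 and 1548, 1069 shared, 42.0% higher) with the replicate number, taken to pair these arrays, as a block and only these 2 groups in the fit. Over every feature 1558 were called, 1208 higher and 350 lower (77.5% higher).

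The next question was how far the responses of the 2 lines overlapped and where they differed. Both lines raised 563 genes, against 174 for independent lists of these lengths, and lowered 462, against 141, while 3 genes were called in opposite directions. The changes correlated at r = 0.768 (rho = 0.706) across genes, which are not independent replicates, and the lines share no array. Of the genes called in TTR cells 95.9% were also called in parental cells and 44 were not. The 1025 genes called the same way fell to 437, 526, 489, 372 and 667 without TTR untreated array 2 or 3 or TTR TRAIL array 1, 2 or 3. They numbered 2852 with array weights and 118 with a change of at least 2-fold. The split turned with the scaling. It was 397 higher and 1888 lower (2285 in all) after median centring, and 427 and 497 after quantile normalization. Genes lower in parental cells had a median of −0.91 there and −0.20 in TTR cells, and 89.0% of the 5508 lay below 0 in TTR cells. Genes higher in parental cells had medians of 0.53 and 0.12, and 81.7% of the 5319 lay above 0.

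**Figure D2:**
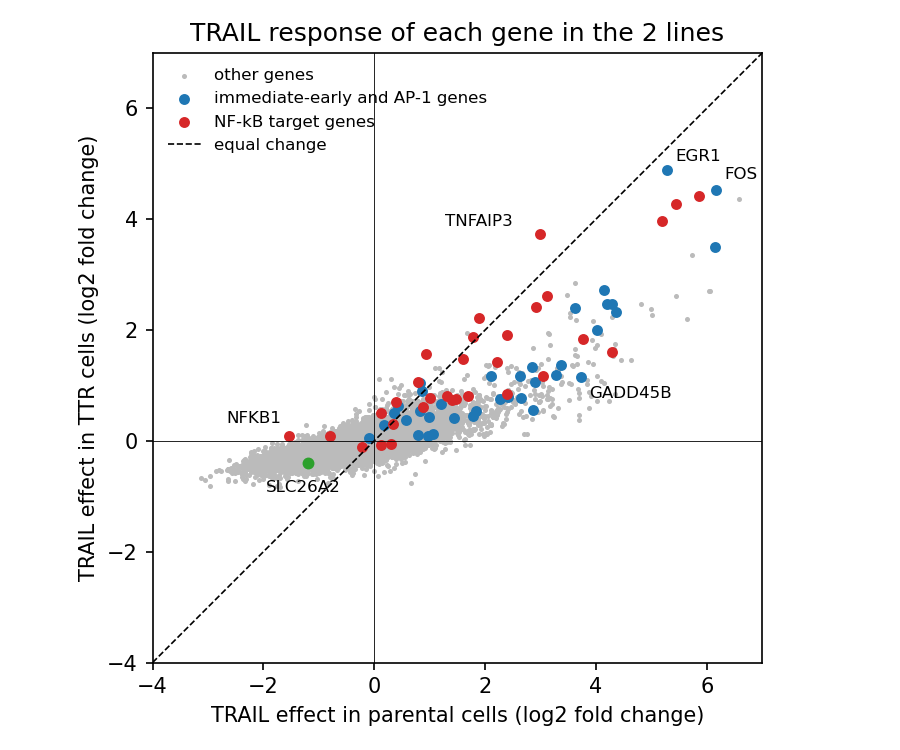
Each point is a gene, with its log2 change by TRAIL in parental cells on the horizontal axis and in TTR cells on the vertical axis. Immediate-early and AP-1 genes are blue, NF-kB targets red, SLC26A2 green and other genes grey. The dashed line marks equal change. FOS lies at 6.17 and 4.53, EGR1 at 5.28 and 4.90, and SLC26A2 at −1.20 and −0.40. As deposited 49.1% of the genes called in parental cells were higher, against 21.3% after median centring.

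The difference between the TRAIL responses was tested directly, as the TTR change minus the parental change. It passed for 6852 genes, 4224 above 0 and 2628 below, and 6790 of these had a change nearer 0 in TTR cells. TRAIL changed 5971 of them in parental cells alone by the threshold, 15 in TTR cells alone and 72 in neither. It changed 791 in both lines the same way, 788 of them by less in TTR cells, and 3 in opposite directions. HSPA2 (−3.51 ± 0.18, adjusted p = 5.79e-09), a chaperone, RASD1 (−3.16 ± 0.19), a small GTPase, SOCS1 (−3.02 ± 0.18), which restrains cytokine signalling, RRAD (−3.01 ± 0.19) and GADD45B (−2.58 ± 0.15) were among the 10 smallest p-values. The others were the testis-associated RNF151 (−3.22 ± 0.16) and 4 small nucleolar RNA or histone genes of multigene families, whose signals are uncertain: SNORD54 (−3.32), SNORD61 (−3.30), H4C9 (−3.29) and H2AC17 (−2.61). Of the immediate-early and AP-1 genes 26 of 36 lay below 0 and 0 above by limma (28 and 0 adjusted over the list alone and at an unadjusted p under 0.05). Their median was −1.32, or −1.13 after median centring (camera adjusted p = 7.68e-15, and adjusted p = 0.0333 with an estimated correlation). FOSB stood at −2.64 ± 0.18, IER2 at −2.02 ± 0.16 and JUND at −2.01 ± 0.16. Of the NF-kB targets 14 of 31 lay below 0 and 3 above, the same adjusted over the list alone, with a median of −0.36, or −0.17 after median centring. Their camera call (adjusted p = 0.0127, and adjusted p = 0.597 with an estimated correlation) was lost without parental TRAIL array 1 (0.0628). The chemokine CCL20 (−2.68 ± 0.35), the prostaglandin synthase PTGS2 (−1.92 ± 0.23) and CXCL3 (−1.89 ± 0.25) had the larger rise in parental cells, while NFKB1 (1.64 ± 0.19) fell there and was at 0.10 in TTR cells.

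Cholesterol, proliferation and NRF2 genes had medians above 0 in the same test. Of 19 cholesterol genes 13 lay above 0 and 2 below (13 and 3 adjusted over the list alone), with SC5D at 1.79 ± 0.16 and SCD at 1.41 ± 0.17 (median 0.66, camera adjusted p = 0.011, and adjusted p = 0.597 with an estimated correlation). Of 32 proliferation genes 17 lay above 0 and 2 below (18 and 2 adjusted over the list alone), among them MCM6 (1.53 ± 0.17), MCM3 (0.94 ± 0.15) and the checkpoint kinase BUB1 (0.92 ± 0.15), with PCNA at −0.96 ± 0.14 (median 0.56, camera adjusted p = 0.011, and adjusted p = 0.597 with an estimated correlation). Of 20 NRF2 genes 9 lay above 0 and 2 below, the same adjusted over the list alone, with PGD at 1.40 ± 0.15, GCLC at 1.32 ± 0.17 and MT1X at −1.86 ± 0.15 (median 0.38, camera adjusted p = 0.0233, and adjusted p = 0.597 with an estimated correlation). After median centring the 3 medians were 0.85, 0.74 and 0.56. The 3 calls were lost without the third of genes with the lowest mean (0.175, 0.175 and 0.252) and after quantile normalization (0.167, 0.375 and 0.108), and that of the NRF2 genes also without TTR untreated array 1 (0.0511). SLC26A2 fell by less in TTR cells (0.81 ± 0.22, adjusted p = 0.0084). Of the receptor list 3 of 11 lay above 0 and 0 below by limma (the same adjusted over the list alone, and 5 and 0 at an unadjusted p under 0.05): TNFRSF11B (0.68 ± 0.19, adjusted p = 0.0093), CFLAR (0.49 ± 0.12, adjusted p = 0.0048) and TNFRSF10A (0.46 ± 0.16, adjusted p = 0.0339). The list itself did not pass (median 0.40, or 0.58 after median centring and 0.14 after quantile normalization, camera adjusted p = 0.360). TNFRSF10A was lost without parental untreated array 1 (0.0671) or 3 (0.0715), parental TRAIL array 1 (0.068) or 2 (0.0752), TTR untreated array 2 (0.0969), TTR TRAIL array 1 (0.0959) or after quantile normalization (0.32, adjusted p = 0.150), over a range of 0.0034 to 0.150. TNFRSF10B did not pass (0.43, adjusted p = 0.0735) but did without parental TRAIL array 2 (0.0373), TTR untreated array 1 (0.0348) or TTR TRAIL array 3 (0.0331), after median centring (0.61, adjusted p = 0.0125) and with array weights (0.0371), over a range of 0.0125 to 0.602. After median centring FADD (0.0487), TRADD (0.0408) and CASP10 (0.0258) passed as well, with ranges reaching 0.898, 0.394 and 0.256, and CASP10 also did after quantile normalization (0.0422), with array weights (0.0332) and without TTR TRAIL array 3 (0.0035). After median centring 80.9% of the called differences were above 0 (5410 above, 1275 below), against 61.6% as deposited.

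The fourth comparison asked how TTR cells differed from parental cells before any TRAIL was added. Both TRAIL death receptors were lower in TTR cells. TNFRSF10A was 2.77-fold lower (−1.47 ± 0.11, adjusted p = 1.06e-06), at 5.17 (SD 0.16) against 6.64 (SD 0.08), and TNFRSF10B was 2.07-fold lower (−1.05 ± 0.13, adjusted p = 7.95e-05). The decoy receptors TNFRSF11B (−0.47 ± 0.13, adjusted p = 0.0419) and TNFRSF10D (−0.44 ± 0.11, adjusted p = 0.016) were also lower. Of the 11 measured receptor and signalling complex genes 4 were lower and 0 higher by limma (5 and 1 adjusted over the list alone and at an unadjusted p under 0.05), with a median of −0.24 (camera adjusted p = 0.0316, and adjusted p = 0.468 with an estimated correlation). CASP8 (−0.30, adjusted p = 0.106) and CFLAR (0.26, adjusted p = 0.0853) did not pass, except with array weights (0.0189 and 0.0254, with ranges reaching 0.302 and 0.411). FADD (0.05), FAS (0.07), TNFSF10 (0.09), CASP10 (−0.24) and TRADD (0.26) did not pass either (adjusted p = 0.908, 0.779, 0.873, 0.516 and 0.394). SLC26A2 was at 6.69 (SD 0.05) in TTR and 6.32 (SD 0.30) in parental cells, a difference of 0.38 ± 0.16 that did not pass (adjusted p = 0.189, and 0.0514 to 0.475 over all alternatives). TNFRSF10D was lost without parental untreated array 2 (0.0596) or 3 (0.0586) or TTR untreated array 2 (0.0854) or 3 (0.0568), over a range of 0.002 to 0.0854. TNFRSF11B was lost without parental untreated array 2 (0.0682) or 3 (0.193) or TTR untreated array 1 (0.0755), 2 (0.169) or 3 (0.0557), after quantile normalization (0.0766) and with only these 2 groups in the fit (0.0777), over a range of 0.0117 to 0.193. The list's call was lost without parental untreated array 3 (0.0918).

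**Figure D3:**
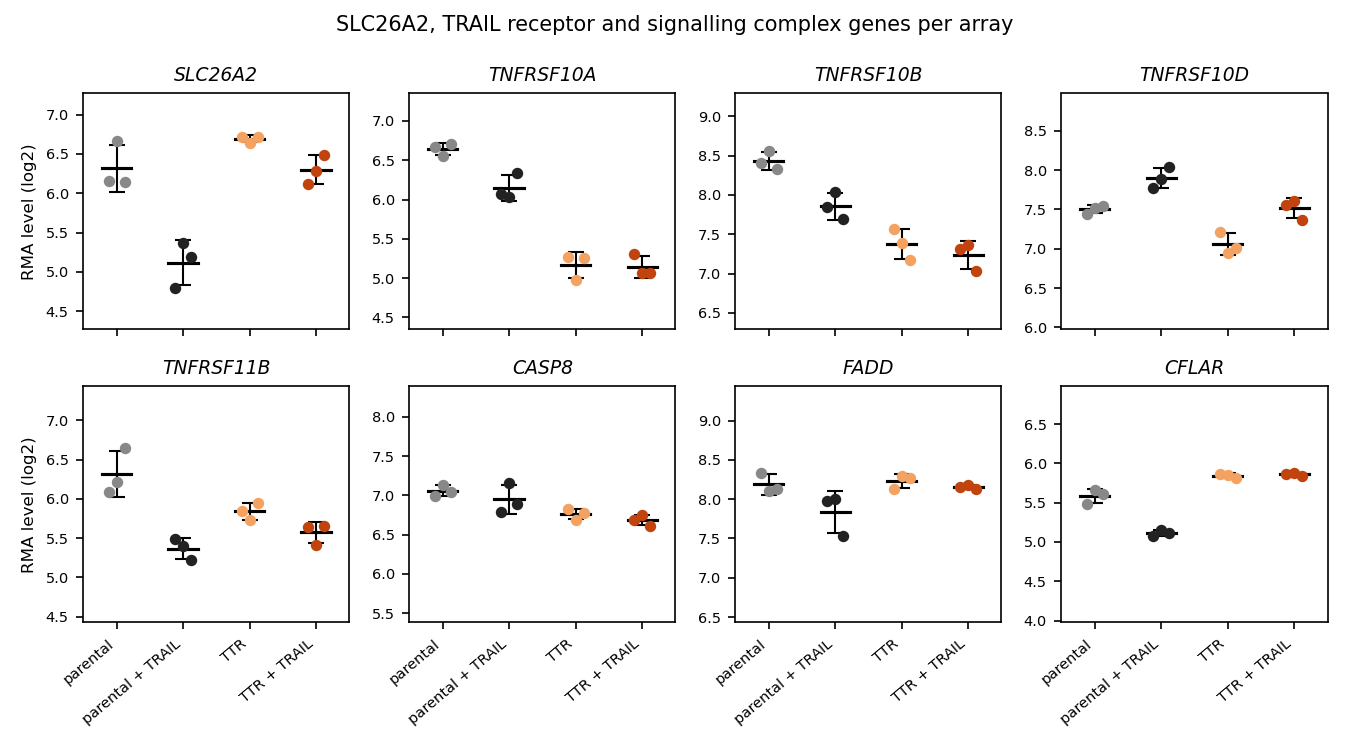
Log2 level (vertical axis) of SLC26A2 and of 7 genes of TRAIL receptors and their signalling complex in the 4 groups. Points are arrays, the black line is the mean and the bar the SD (n = 3), and each panel spans the same log2 range from a different start. TNFRSF10A was at 6.64 in untreated parental and 5.17 in untreated TTR cells, and SLC26A2 at 6.32 and 6.69.

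The largest differences between the untreated lines lay outside the death receptor pathway. MAGEB2, a cancer-testis antigen, was 19.6-fold lower in TTR cells (−4.29 ± 0.11, adjusted p = 8.88e-13), and the forkhead factor FOXR2 12.2-fold lower (−3.61 ± 0.12). Also lower were the aldolase ALDOC 6.62-fold (−2.73 ± 0.12), the collagen chaperone FKBP10 5.77-fold (−2.53 ± 0.14) and the actin-bundling LCP1 4.88-fold (−2.29 ± 0.13). The matrix protease ADAMTS1 was 4.60-fold higher (2.20 ± 0.15), the cadherin CDH18 4.42-fold (2.14 ± 0.13), the BMP antagonist NOG 3.79-fold (1.92 ± 0.17) and the integrin ITGB8 3.74-fold (1.90 ± 0.22). Cholesterol genes were higher as a group. Of 19, 7 were higher and 0 lower by limma (14 and 1 adjusted over the list alone and at an unadjusted p under 0.05), with a median of 0.35 (camera adjusted p = 5.31e-07, and adjusted p = 0.102 with an estimated correlation). Among them were the sterol dehydrogenase NSDHL (0.49 ± 0.10, adjusted p = 0.006) and INSIG1 (0.41 ± 0.09, adjusted p = 0.0067), the sterol-regulated brake on this pathway. Of 12 antigen presentation genes 4 were higher and 1 lower (6 and 1 adjusted over the list alone), with a median of 0.34 (camera adjusted p = 0.0016, and adjusted p = 0.102 with an estimated correlation). The higher ones included the class II genes HLA-DMA (1.00 ± 0.16), HLA-DPA1 (0.82 ± 0.15) and HLA-DPB1 (0.67 ± 0.10), which belong to a multigene family and are uncertain. Of 34 interferon-stimulated genes 6 were lower and 0 higher by limma (7 and 3 adjusted over the list alone, 10 and 4 at an unadjusted p under 0.05), with IFI44 at −0.98 ± 0.12, OAS2 at −0.93 ± 0.10 and USP18 at −0.70 ± 0.12. The list's median was −0.15 (camera adjusted p = 0.0273, and adjusted p = 0.468 with an estimated correlation), a call lost without parental untreated array 3 (0.0918) or TTR untreated array 1 (0.0631). Ribosomal protein genes had a median of −0.09 (camera adjusted p = 0.0324, and adjusted p = 0.615 with an estimated correlation), although 0 of 23 passed by limma, 0 adjusted over the list alone and 2 at an unadjusted p under 0.05, with RPLP2 at −0.25 and RPL11 at −0.24. That call was lost without parental untreated array 1 (0.0592) or 3 (0.11), TTR untreated array 1 (0.296) and the third of genes with the lowest mean (0.0585).

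Without TRAIL 1310 genes (7.11%) differed between the lines, 671 higher and 639 lower in TTR cells, with 67 higher and 42 lower by at least 2-fold. The count was 807 without parental untreated array 1, 829 without parental untreated array 2, 782 without TTR untreated array 2, 2386 with array weights, and 1654 (1290 shared) with the parental TRAIL arrays out of the fit.

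The last comparison set the lines side by side after TRAIL, which includes the parental arrays that stood apart. SNAI1 was 13.7-fold lower in TTR cells (−3.77 ± 0.16, adjusted p = 1.62e-10), ID2 11.6-fold (−3.54 ± 0.30), the stress gene GADD45G 11.2-fold (−3.49 ± 0.18) and HSPA2 10.5-fold (−3.39 ± 0.12). Of the 36 immediate-early and AP-1 genes 31 were lower and 2 higher (31 and 4 adjusted over the list alone), with FOSB at −2.65 ± 0.13, GADD45B at −2.26 ± 0.11 and IER2 at −2.10 ± 0.11. The median was −1.27, or −1.07 after median centring (camera adjusted p = 1.10e-11, and adjusted p = 0.0681 with an estimated correlation). Of 31 NF-kB targets 18 were lower and 4 higher, the same adjusted over the list alone, including CXCL10 (−1.82 ± 0.17), CXCL3 (−1.77 ± 0.18) and, higher, CYLD (1.28 ± 0.10). The median was −0.48, or −0.28 after median centring, and the camera call (adjusted p = 0.0143, and adjusted p = 0.580 with an estimated correlation) was lost without parental TRAIL array 1 (0.0534). MSMO1 was 6.76-fold higher in TTR cells (2.76 ± 0.17), HACD3 6.73-fold (2.75 ± 0.21), the matrix protein EFEMP1 5.81-fold (2.54 ± 0.17) and PAPSS2, which makes the sulfate donor PAPS, 5.47-fold (2.45 ± 0.17). Cholesterol genes were higher in 15 and lower in 1 of 19 (15 and 2 adjusted over the list alone), with SC5D 4.78-fold higher (2.26 ± 0.12). Their median was 1.06, or 1.26 after median centring (camera adjusted p = 1.19e-04, and adjusted p = 0.257 with an estimated correlation). Of 32 proliferation genes 20 were higher and 3 lower (21 and 3 adjusted over the list alone), such as MCM6 (1.32 ± 0.12) and CCNA2 (1.13 ± 0.10), with a median of 0.64 (camera adjusted p = 0.0011, and adjusted p = 0.580 with an estimated correlation). Of 20 NRF2 genes 11 were higher and 2 lower, the same adjusted over the list alone, with NQO1 at 1.64 ± 0.12 and MT1X at −1.89 ± 0.11 and a median of 0.44 (camera adjusted p = 0.0182, and adjusted p = 0.551 with an estimated correlation). The proliferation and NRF2 calls were lost without the third of genes with the lowest mean (0.0635 and 0.115) and after quantile normalization (0.0836 and 0.0606).

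SLC26A2 was higher in TTR than in parental cells under TRAIL (1.18 ± 0.16, adjusted p = 7.25e-06), at 6.30 (SD 0.19) against 5.12 (SD 0.29). Of the 11 receptor and signalling complex genes 3 were higher and 4 lower, the same adjusted over the list alone, and the list did not pass (camera adjusted p = 0.933). Its median of −0.07 changed sign with the scaling, to 0.13 after median centring (5 higher, 2 lower) and 0.08 after quantile normalization. TNFRSF10A (−1.01 ± 0.11), TNFRSF10B (−0.63 ± 0.13), TNFRSF10D (−0.39 ± 0.11) and CASP8 (−0.27 ± 0.10) were lower, and CFLAR (0.75 ± 0.09), TRADD (0.66 ± 0.15) and FADD (0.32 ± 0.12) were higher. TNFRSF11B (0.21, adjusted p = 0.199), CASP10 (0.27, adjusted p = 0.184), FAS and TNFSF10 (−0.07 each, adjusted p = 0.583 and 0.755) did not pass. CASP8 (adjusted p = 0.0386) was lost without parental TRAIL array 2 (0.177) or TTR TRAIL array 1 (0.0776), 2 (0.0526) or 3 (0.12), after median centring (−0.06, adjusted p = 0.633), with only these 2 groups in the fit (0.0746) and with array weights (0.0742), over a range of 0.0024 to 0.633. FADD (adjusted p = 0.0342) was lost without parental TRAIL array 3 (0.195) or TTR TRAIL array 1 (0.0731), 2 (0.0855) or 3 (0.0617), after quantile normalization (0.08, adjusted p = 0.626) and with only these 2 groups in the fit (0.0584), over a range of 0.0018 to 0.626, and it stood at 0.52 after median centring. TNFRSF10D was lost after median centring (−0.18, adjusted p = 0.158, range 8.88e-05 to 0.158). TNFRSF11B passed after median centring (0.41, adjusted p = 0.0138, range 0.0138 to 0.465), and CASP10 after median centring (0.0223) or quantile normalization (0.0476) and without TTR TRAIL array 3 (0.004), over a range of 0.004 to 0.548.

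With TRAIL 10017 genes (54.4%) differed between the lines, 5164 higher and 4853 lower in TTR cells, with 1924 higher and 506 lower by at least 2-fold. As deposited 51.6% of them were higher, against 74.1% (6839 higher, 2391 lower) after median centring, and over every feature it was 42.8% (6584 higher, 8783 lower). Without and with TRAIL 577 genes were higher in TTR cells both times, against 188 for independent lists, 279 were lower both times, against 168, and 151 changed direction. The differences correlated at r = 0.368 (rho = 0.304) across genes, which are not independent replicates. The 856 genes called the same way were 547 without parental untreated array 1, 533 without TTR untreated array 2, 1437 with array weights and 66 with a difference of at least 2-fold.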

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

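The tests that weigh explanations in this part were set before their results were seen, while TNFAIP3, the NF-kB targets that rose by more in TTR cells, and the sorting of the redrawn labels by whether they part the TRAIL arrays were looked at afterwards. Groups of 3 arrays are too small to test single arrays for standing apart. The intervals in this part come from resampled genes, which are not independent replicates, and leave out the spread between arrays.

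The TRAIL response differed between the lines for 6852 genes by a direct test of the difference. The 10 genes with the smallest p were H2AC17 (−2.61), H4C9 (−3.29), HSPA2 (−3.51), RASD1 (−3.16), RNF151 (−3.22), RRAD (−3.01), SNORD54 (−3.32), SNORD61 (−3.30), SOCS1 (−3.02) and GADD45B (−2.58), as TTR minus parental change on the log2 scale. SLC26A2 (0.81), TNFRSF11B (0.68), CFLAR (0.49) and TNFRSF10A (0.46) differed the other way. The call of TNFRSF10A was lost when any 1 of these was left out: parental untreated arrays 1 (0.0671) and 3 (0.0715), parental TRAIL arrays 1 (0.068) and 2 (0.0752), TTR untreated array 2 (0.0969) and TTR TRAIL array 1 (0.0959). It was also lost after quantile normalization (0.150), over a range of 0.0034 to 0.150. Among lists, immediate-early and AP-1 genes (camera adjusted p = 7.68e-15, and adjusted p = 0.0333 with an estimated correlation) and NF-kB targets (0.0127, and 0.0628 without parental TRAIL array 1) lay below 0. Proliferation genes (0.011), cholesterol genes (0.011) and NRF2 genes (0.0233, and 0.0511 without TTR untreated array 1) lay above 0. For NF-kB targets and each of these 3 lists adjusted p = 0.597 with an estimated correlation. The calls above 0 were also lost without the third of genes with the lowest mean (0.175, 0.175 and 0.252) and after quantile normalization (0.375, 0.167 and 0.108). Line labels were redrawn 100 times within the untreated and within the TRAIL arrays, out of 200 distinct assignments. The real assignment gave 6852 genes, 7 of the 100 draws including it gave as many, and the highest other gave 8595. In the 8 draws that keep the TRAIL arrays of each line together, and so keep the line difference under TRAIL, 7 were as large and the lowest gave 6338, while the highest of the 92 that mix them gave 4. The draw with 8595 was the full exchange of the line labels among the TRAIL arrays. As draws of the first kind hold the difference under TRAIL by design, the share over all draws says nothing for or against chance.

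The first pattern weighed is the broad shift of the 3 TRAIL-treated parental arrays. Poor RNA or array quality in those arrays alone would leave the genes that fell there on both sides of 0 in the TTR arrays. Instead 89.0% of these 5508 genes lay below 0 in the TTR response, and 83.3% to 89.9% did in each TTR TRAIL array. Over all genes, not matched on level, it was 51.5%. This argues against poor quality of those 3 arrays alone as the whole cause. It cannot speak to quality shared by the TRAIL arrays of both lines, which would lower the same genes in both. A common distribution imposed by RMA on samples that lost RNA overall stays open, since without a spike-in neither the median change of all genes as deposited (0.0548) nor after median centring (−0.24) bounds an overall loss. A response to TRAIL that is larger in parental cells, as the design would allow, also stays open and may act together with it.

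The second pattern is that the TTR response reached a larger share of the parental change for NF-kB targets than for genes that fell. On the linear scale the median share was 56.9% for 26 called NF-kB targets and 27.1% for the genes called lower. If a fixed share of TTR cells had responded exactly as parental cells do, the ratio of these shares would be near 1. It was 2.10 (95% interval over resampled genes 1.45 to 2.87). The lower end lies just below the bound of 1.5 set beforehand, so this explanation is not excluded, and although 6 of the 26 rose by more in TTR cells, which no such share gives, that difference was called for TNFAIP3 alone (adjusted p = 0.0488, range over alternatives 0.0066 to 0.186). Saturation of bright NF-kB probes could also give such a ratio, but among 21 targets below a level of 10 in every group it was 2.37 (interval 1.38 to 3.33), with a median share of 64.4%, which leaves it open too.

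The third pattern is the lower TNFRSF10A and the other differences of untreated TTR cells. Cells of another type among the TTR cells would raise their markers. The 42 markers of luminal, blood, fibroblast and endothelial cells had a median difference of −0.0493 (interval −0.13 to −0.02). Among them 1 was higher and 3 lower (exact binomial test for an excess of higher calls, one-sided p = 0.790). Cells of 1 kind would raise only their own markers, so these pooled values cannot decide the question. By list the medians were −0.0783 (luminal), −0.1234 (blood) and −0.024 (fibroblast and endothelial), so no list had a median above 0. Only 20 markers lie above the third of genes with the lowest mean. The luminal KRT8 and KRT18 were already at 10.47 and 10.49 in parental cells. Cells of another type therefore stay open. TRAIL signalling still running in untreated TTR cells would hold NF-kB targets up. The 24 that TRAIL raised in TTR cells had a median difference of −0.0456 (interval −0.18 to 0.06), against a change of 1.53 with TRAIL. These 24 were picked by their rise from the same untreated TTR arrays, which favours genes low there, so their median cannot decide the question. All 31 measured NF-kB targets, a list fixed beforehand, had a median difference of −0.03. Of these, 3 were higher and 3 lower by limma (camera adjusted p = 0.887), so the fixed list showed no rise. A stable difference between the lines stays open as an untested biological explanation, as does whatever the unexplained tag of the sample descriptions marks, since it differs with the line.

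For the other 4 comparisons the 6 arrays allow 10 splits, too few for a share under 0.05. In each, 1 split, the real one, gave as many genes, and the highest other gave 0 by limma, whether or not a split parts same-numbered arrays. Every other split mixes the 2 groups, which puts any real difference into the spread. Its 0 therefore does not measure how many calls arise by chance. The real counts were 10827 for TRAIL in parental cells, 1072 for TRAIL in TTR cells, 1310 for TTR against parental cells without TRAIL and 10017 with TRAIL. At an unadjusted p under 0.05 the real splits gave 11478, 3794, 3475 and 10930.

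Of 12038 features with no gene named here, which the comparisons did not use, TRAIL changed 5127 in parental cells (3812 higher, 1315 lower) and 651 in TTR cells (606 higher, 45 lower). TTR and parental cells differed in 124 of them without TRAIL (45 higher, 79 lower in TTR cells) and in 4420 with TRAIL (1133 higher, 3287 lower). Their median level was 3.32, so many may be background. Their median change with TRAIL was 0.16 in parental and 0.03 in TTR cells. The same measure was lower over every feature (0.105 and 0.0091) and over named features (0.0717 and −3.18e-04). The rise in the median of all features (0.29 and 0.11), which median centring would subtract, is another measure and was larger. The counts of called features given here were not recomputed with another scaling.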

How the results depend on the processing

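Leaving the 3 TRAIL-treated parental arrays out of the fit, and the block with only the 2 TTR groups in it, were chosen after the data were seen, and all other alternatives beforehand. Counts of called genes stayed within 1.5 times the reported count, and lists within that factor, except as follows. The cause was not tested where none is given. Every feature of the table, which tests more items, gave 17193 calls for TRAIL in parental cells and 15367 for the lines with TRAIL. Requiring at least 2-fold, a stricter rule by construction, gave 3215 (TRAIL in parental cells), 124 (TRAIL in TTR cells), 109 (lines without TRAIL), 2430 (lines with TRAIL) and 2099 (difference of the TRAIL effects), with 118 shared by the TRAIL responses and 66 by the differences between lines. Array weights gave 3199 for TRAIL in TTR cells, 2386 for the lines without TRAIL, 2852 shared by the TRAIL responses and 1437 by the line differences. Median centring gave 2391 for TRAIL in TTR cells, 918 of them among the 1072 reported, and 2285 shared. Its construction explains the turn of the split, since it subtracts array medians that were higher with TRAIL. Without the parental TRAIL arrays TRAIL in TTR cells gave 1709.

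The reported number of lists was 5 for TRAIL in parental cells, 2 in TTR cells, and 5 in each other comparison. It was 2 in parental cells, 3 for the lines with TRAIL and 2 for the difference both without the third of genes with the lowest mean and after quantile normalization, and 2 in parental cells after median centring. camera with an estimated correlation called 1, 2, 0, 0 and 1, in the order parental TRAIL, TTR TRAIL, lines without TRAIL, lines with TRAIL and difference. fry, which does not compare a list with other genes, called 19, 3, 6, 14 and 11.

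Leaving out each array in turn gave 379 to 1443 genes for TRAIL in TTR cells, 782 to 1316 for the lines without TRAIL, 372 to 1417 shared by the TRAIL responses and 533 to 1006 by the line differences. The lists called for the lines without TRAIL ranged from 2 to 8: 2 without parental untreated array 3, 3 without TTR untreated array 1 and 8 without TTR untreated array 3. The genes for TRAIL in TTR cells were 450 and 542 without TTR untreated arrays 2 and 3, and 508, 379 and 693 without TTR TRAIL arrays 1, 2 and 3. The lines without TRAIL gave 807, 829 and 782 without parental untreated arrays 1 and 2 and TTR untreated array 2. For genes shared by the TRAIL responses the low values were 437, 526, 489, 372 and 667 without those same 5 TTR arrays, and for the line differences 547 and 533 without parental untreated array 1 and TTR untreated array 2.

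Of 7563 alternative values for 500 single-gene results, 7151 kept direction and side of the threshold, 328 lost the call (85 results), 47 gained it (20 results), 35 changed sign without a call (13 results) and 2 reversed, both after median centring in TRAIL-treated parental cells: KRT18 to −0.0297 and PTPRC to −0.0434, neither called there. Without a measure of signal over background, low levels limit the weight of single genes.

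With the replicate number as a block the counts were 11138, 1567, 1672, 10384 and 7276 in the order above, 1487 and 1098 shared, and 5, 2, 7, 5 and 5 lists. The block gave a call to the mesenchymal and sulfation lists without TRAIL (0.0483 each), and among single genes to TNFRSF10B for the difference (0.0213, range over alternatives 0.0125 to 0.602), GALNT1 for TRAIL in TTR cells (−0.43, adjusted p = 0.039, range 0.0102 to 0.261) and PHGDH without TRAIL (−0.58, adjusted p = 0.0182, range 0.0177 to 0.242). It changed no other call of a named gene or list. By the bound of 0.1 on each correlation, the numbers were taken to pair TTR cells without and with TRAIL. The groups of the other comparisons did not meet this bound, which does not show that they are unpaired. Number 3 of untreated parental and untreated TTR arrays, for example, correlated at 0.373. The block in a fit of these 2 groups alone gave 2670 genes and 2 lists, ended no call of a named gene, and gave one to SLC26A2 (0.0258, range 0.0258 to 0.426), TNFSF10 (0.0101, range 0.0101 to 0.561), GALNT1 (0.0102), C1GALT1 (−0.38, adjusted p = 0.0385, range 0.0108 to 0.425) and CLDN5 (0.40, adjusted p = 0.020, range 0.0049 to 0.279). Of 18 correlations between same-numbered arrays of different groups 8 were over 0.1 (range −0.055 to 0.395, mean 0.125), and 9 of 12 arrays correlated best with their own number.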

Other observations

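The tests on small nucleolar RNA and clustered histone genes below were chosen after their results were seen, and the nuclear RNA test before. Their intervals and random lists again rest on resampled genes, not arrays. ETS1, TNFAIP3 and the other genes singled out for the direction of their change were chosen after their values were seen.

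DDIT3, PLK3 and CDKN1A rose with TRAIL in both lines, while the stress response and p53 lists that hold them did not pass as reported. DDIT3, a transcription factor of the integrated stress response, rose 8.80-fold in parental (3.14 ± 0.16 SE) and 2.80-fold in TTR cells (1.49 ± 0.16), the kinase PLK3 12.5-fold and 4.54-fold, and the cell cycle inhibitor CDKN1A 4.47-fold and 2.22-fold. Of 26 unfolded protein and stress response genes 13 rose and 11 fell in parental cells, the same adjusted over the list alone (median 0.19, camera adjusted p = 0.545, and −0.10 with 11 and 13 after median centring). In TTR cells 4 rose and 2 fell (10 and 6 adjusted over the list alone, 4 and 6 after median centring, adjusted p = 0.200, and 0.0286 after quantile normalization). Of 18 p53 targets 6 rose and 8 fell in parental cells, the same adjusted over the list alone (adjusted p = 0.882, median 4.83e-04, and −0.29 after median centring). In TTR cells 3 of the p53 targets rose and 0 fell by limma (3 and 1 adjusted over the list alone, 3 and 3 at an unadjusted p under 0.05 and after median centring), and there the median (−0.10, or −0.21 after median centring) and mean (0.15) differed in sign. The apoptosis lists split as well. Of 19 caspases and pro-apoptotic genes 6 rose and 9 fell in parental cells (7 and 9 adjusted over the list alone, adjusted p = 0.819): the BH3-only genes PMAIP1 (1.38 ± 0.12) and BBC3 (1.19 ± 0.13) rose, and CASP6 (−1.88 ± 0.15) and BID (−1.36 ± 0.12), which links death receptors to mitochondria, fell. Of 12 anti-apoptotic genes 3 rose and 6 fell (4 and 6 adjusted over the list alone, 1 and 8 after median centring, adjusted p = 0.545), with MCL1 rising in parental (1.35 ± 0.10) and TTR cells (0.80 ± 0.10) and BCL2L1 (−0.59 ± 0.09) falling in parental cells. Of 23 hypoxia and glycolysis genes 6 rose and 13 fell in parental cells (6 and 15 adjusted over the list alone, adjusted p = 0.231), the vasodilator peptide gene ADM by 3.84 ± 0.18 and the glycolytic enzyme PGK1 by −1.63 ± 0.11.

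Of 27 sulfation genes 12 rose and 10 fell with TRAIL in parental cells, the same adjusted over the list alone, and 4 and 11 after median centring (adjusted p = 0.985), and the median (0.10), mean (−0.12) and median after centring (−0.20) differed in sign. The sulfate donor transporter SLC35B2 (−1.54 ± 0.10) and PAPSS1 (−1.52 ± 0.14) fell and HS6ST1 (1.73 ± 0.11) rose. Of 9 measured SLC26 transporters 3 rose and 1, SLC26A2, fell, the same adjusted over the list alone (median 0.25, and −0.04 after median centring, adjusted p = 0.399). These counts were 2 and 2 after median centring and 1 and 1 after quantile normalization. Of 16 genes of death receptor O-glycosylation 2 rose and 8 fell, the same adjusted over the list alone (median −0.39, or −0.68 after median centring, adjusted p = 0.231). GALNT1, which starts O-glycans, fell 5.75-fold (−2.52 ± 0.14) and C1GALT1, which extends them, 3.24-fold (−1.70 ± 0.15), and both were higher in TTR than in parental cells under TRAIL (1.85 ± 0.14 and 2.02 ± 0.15). Without TRAIL the mesenchymal genes MMP1 (1.54 ± 0.12) and SNAI2 (1.14 ± 0.11) were higher and COL6A1 (−1.03 ± 0.13) lower in TTR cells, and of the 29 on the list 4 were higher and 2 lower (6 and 2 adjusted over the list alone, adjusted p = 0.0575). That list passed without parental untreated array 2 (0.0174), TTR untreated array 2 (0.0495) or 3 (0.0137), or the third of genes with the lowest mean (0.045). Of 28 epithelial genes 1 was higher and 1 lower, the same adjusted over the list alone (adjusted p = 0.887). Of 15 luminal markers 2 were lower and 0 higher by limma (3 and 1 adjusted over the list alone and at an unadjusted p under 0.05, adjusted p = 0.218 for the list), with TFF3 at −1.32 ± 0.13. Of 13 blood markers 0 passed by limma, 0 adjusted over the list alone and 0 at an unadjusted p under 0.05 (adjusted p = 0.364). Of 14 fibroblast and endothelial markers 1 was higher and 1 lower, the same adjusted over the list alone (adjusted p = 0.887). The lower one was PECAM1 (−0.87 ± 0.16, adjusted p = 0.0033), whose features differed in sign in at least one comparison. The higher one, KDR (0.51 ± 0.13, adjusted p = 0.0196), was chosen after its value was seen. It was lost without parental untreated array 2 (0.0665) or 3 (0.096) or TTR untreated array 1 (0.058) or 2 (0.0907), over a range of 0.0031 to 0.096. The luminal markers KRT18 and KRT8, which the epithelial list also holds, were at 10.49 and 10.47 in parental and 10.45 and 10.95 in TTR cells. The features of KRT18 differed in sign in at least one comparison.

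A few genes went against the smaller TTR response. ETS1, a transcription factor, fell in parental (−0.34 ± 0.10) and rose in TTR cells (0.49 ± 0.10), a difference of 0.82 ± 0.14 (adjusted p = 2.20e-04, range over alternatives 3.02e-05 to 0.0024). Its fall in parental cells was lost after quantile normalization (−0.0818, adjusted p = 0.533, range 4.77e-05 to 0.533). OR52K3P (0.67 and −0.76) and LOC442028 (0.35 and −0.49), both at low levels, rose in parental and fell in TTR cells. The fall of OR52K3P was lost without TTR TRAIL array 2 (0.0697, the highest over its alternatives), and its rise after median centring (0.0535, range 4.25e-05 to 0.0535). The fall of LOC442028 was lost without TTR untreated array 2 (0.177) or 3 (0.0847) or TTR TRAIL array 1 (0.0928), 2 (0.123) or 3 (0.119), over a range of 0.0018 to 0.177. Its rise was lost without parental untreated array 2 (0.140) or parental TRAIL array 2 (0.175) and with either scaling, only these 2 groups in the fit (0.0535) and array weights (0.058), over a range of 0.0064 to 0.706.

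TNFAIP3 (3.00 in parental and 3.73 in TTR cells), CSF1 (0.43 and 0.85) and the olfactory receptor gene OR4F15 (0.35 and 0.97) were the 3 genes called in both lines with a called difference in favour of TTR cells (adjusted p = 0.0488, 0.0267 and 0.0183). None of the 3 differences held when each array was left out in turn. That of TNFAIP3 was lost without parental untreated array 2 (0.116) or 3 (0.0906), parental TRAIL array 2 (0.125) or 3 (0.112), TTR untreated array 2 (0.0927) or 3 (0.112), or TTR TRAIL array 1 (0.0957) or 2 (0.130) and after quantile normalization (0.186), over a range of 0.0066 to 0.186. That of CSF1 was lost without parental untreated array 2 (0.0516) or 3 (0.0669), parental TRAIL array 2 (0.0593), TTR untreated array 2 (0.0736), or TTR TRAIL array 2 (0.0521) or 3 (0.053) and after quantile normalization (0.377), over a range of 0.0023 to 0.377. Its rise in parental cells was lost after median centring (0.14, adjusted p = 0.218, range 2.75e-05 to 0.218). That of OR4F15 was lost without parental TRAIL array 2 (0.0514) or TTR TRAIL array 2 (0.0586), over a range of 0.0017 to 0.0586. Its rise in parental cells was lost without parental untreated array 1 (0.0849), 2 (0.0806) or 3 (0.067) or parental TRAIL array 1 (0.0573) or 3 (0.188) and with either scaling, over a range of 0.0147 to 0.728.

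A hypothesis for the broad shift in TRAIL-treated parental arrays is that polyadenylated mRNA was lost relative to RNA that lacks a poly(A) tail or stays in the nucleus. Loss of mRNA with sparing of non-coding RNA is known in apoptosis after mitochondria are permeabilised. The 7 nuclear long non-coding RNAs of a list written beforehand had a median change of 0.79 (interval 0.16 to 1.39) in parental cells, with 5 of them higher, where 95% of random lists matched on level lay between −1.18 and 0.27. Small nucleolar RNAs had a median of 1.01 over 192 genes (interval 0.80 to 1.22, 133 higher and 1 lower, random lists −0.08 to 0.03), and clustered histone genes 0.50 over 51 genes (interval 0.29 to 0.92, 34 higher and 1 lower, random lists −0.42 to 0.07). In TTR cells the medians were 0.14, 0.14 and 0.08, also above the upper random bounds of 0.11, −5.59e-04 and 0.03. There limma called 0, 37 and 11 higher and 0 lower in each class (1, 56 and 14 higher and 0, 0 and 1 lower at an unadjusted p under 0.05). After median centring the medians were 0.50, 0.72 and 0.21 in parental cells, with 4, 115 and 23 higher and 1, 24 and 4 lower. In TTR cells they were 0.03, 0.03 and −0.03, where the last turned sign. Centring moves every gene of a comparison by the same amount, random lists included. It therefore leaves the position of these medians relative to those lists unchanged. The nuclear RNA value, the one test set beforehand, is in line with the hypothesis. The other two tests were chosen once such genes had been seen among the smallest p-values, so they describe the pattern and add no independent support. A relative measure may show the same if these classes rose by themselves, and many of these genes belong to families whose probes may cross-react.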
